A study of Homo sapiens with 17 samples.

How the data were processed

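RNA was measured in 17 libraries of the BEAS-2B line: 6 controls, 6 exposed to 10 mM and 5 exposed to 16 mM acetaldehyde for 24 h. Per the labels' protocols, total RNA was enriched for poly-A messenger RNA, fragmented, reverse transcribed from random primers and made into circularised single-strand libraries. Whether the libraries keep strand is not given in the sources used here, so antisense and overlapping genes cannot be told apart. Groups and replicate numbers were taken from the sample titles. The labels name no batch.

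The authors' deposited table lists 16884 genes, all of them protein-coding. Per the submitters' processing notes, HISAT (no version), Bowtie2 2.3.4.3, RSEM 1.3.1 and DESeq2 1.4.5 are named with genome build GRCh38.p13. Their roles are not stated. The deposited values named read counts, per the file headers, were taken as estimated counts per gene without normalization, since 13.1% of them are not whole and their sums differ between libraries. The deposited FPKM values, so named per the file headers, are by the definition of that unit scaled for transcript length and for the depth of each library. The deposited TPM columns sum to between 999999.24 and 1000000.22 and served only as a check of the table. The log2 fold changes and the p-values and q-values of the authors' own DESeq2 comparisons stand in the same deposited table, per the file headers, and were used only where the authors' deposited table is named. Each per-sample column matched 1 sample, with 0 left over.

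Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3; glmQLFit and glmQLFTest) after TMM normalization, on the 12564 genes that filterByExpr kept for the 3 groups. These held at least 99.95% of the counts of each library. One fit over all 17 libraries, with 14 residual degrees of freedom and no block, gave the 3 comparisons. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. A count of larger changes required a log2 change of at least 1 in size (2-fold). Levels in the text are FPKM, as mean ± SD over libraries, and changes are log2 estimates from edgeR ± SE. The SE is not an output of edgeR: it was derived as the size of the log2 change divided by the square root of the test's F statistic. Total counts lay between 15952673 and 18809242 per library. Adjusted p-values measure the spread between libraries.

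Gene lists numbering 46 were written down in advance, and 45 had a tested member. For each list the called members were counted over all genes and adjusted over the list alone. Among all 12564 tested genes, 2351 were called at 10 mM, 4439 at 16 mM and 1777 between the doses. Without 10 mM library 1 these were 5670, 8271 and 5537 of 12545. Counts of list members are to be read against these shares. Limma 3.58.1 gave camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over lists within a comparison. KEGG pathways named in the deposited table with 10 to 500 tested members (327 pathways) were tested in the same way, and Hallmark sets were added after the table was seen. Camera compares a list with the other genes, while fry asks whether the members move in 1 direction on balance. Numbers of detected genes (at least 10 counts) were compared by an exact two-sided permutation test. For the overlap of both doses, unchanged groups were simulated 20 times against the same controls, and the controls were also split.

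Named genes followed a rule: per comparison, the 8 largest rises and the 8 largest falls among called genes with at least 5 FPKM in the higher group and no overlap between the libraries of both groups. It also took up to 4 called members per list with at least 1 FPKM, or up to 2 with the smallest p where none was called, members of the PI3K-AKT, FOXO, MAPK-ERK and ERK output lists, and 40 anchor genes. The text names part of the genes the rule takes, and some are not reported here. Coordinates are those of the deposited table. The groups, tests, lists, this rule and the alternatives not marked as added were chosen before the data were examined.

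The fitting code was tested on simulated data drawn from the means and library sizes of the 12564 genes, with 50 genes changed at each fold. For 10 mM against control it recovered 30% of 1.5-fold, 86% of 2-fold, 100% of 4-fold and 100% of 8-fold changes, with 10 false calls among 168. For 16 mM against control it recovered 28%, 70%, 96% and 98%, with 7 false calls among 153.

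Alternatives were a block for the replicate number, DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, limma on log2(FPKM + 1) with at least 1 FPKM in at least 5 libraries, limma voom with library weights, only the groups compared, and each library left out in turn. Added after the data were seen were the block without 10 mM library 1 and sums of libraries lying close together. Fits split by those close libraries were also tried and were left out, because such a split comes from the measured values. The sums share this limit and are kept as a check only. Spans, transcript lengths and GC content came from GENCODE annotation 29, which matched 12472 of the tested genes (99.3%). A planned share of counts in mitochondrially encoded genes was not computed, because none of those genes is listed in the table. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 served for tables and plots.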

Results

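Messenger RNA was profiled in BEAS-2B, an immortalised line of human bronchial epithelial cells, after 24 h in medium with 0, 10 or 16 mM acetaldehyde, a reactive aldehyde that arises from ethanol and is present in tobacco smoke. Estimated counts per library totalled 16618130 to 17181707 in control, 16622786 to 18809242 at 10 mM and 15952673 to 17245285 at 16 mM. Of 16884 protein-coding genes in the table, 12564 had enough counts to be tested. The number of genes with at least 10 counts was 12403 ± 84.3 (SD, n = 6) in control, 12248 ± 285 (n = 6) at 10 mM and 12226 ± 156 (n = 5) at 16 mM. The exact two-sided permutation test of these numbers gave p = 0.225 (adjusted p = 0.338 over 3 comparisons) for 10 mM against control, p = 0.0281 (adjusted p = 0.0843) for 16 mM against control and p = 0.896 (adjusted p = 0.896) for 16 mM against 10 mM.

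Library 1 of the 10 mM group stood apart. Its log2 expression correlated across genes at r between 0.840 and 0.866 with the other 10 mM libraries, whereas every other pair within a group had r of at least 0.977. Its 10 most abundant genes took 6.08% of its counts, against at most 3.45% in any other library, and its median gene stood at 2.62 FPKM, against at least 6.71 FPKM in the others. Its TMM factor was 0.559, against at least 0.967 in the others. FPKM are not scaled by that factor, so its FPKM stand lower against other libraries than on edgeR's scale. Counts of genes and of list members are also given without 10 mM library 1 below, a choice made after its values were seen. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

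**Figure D1:**
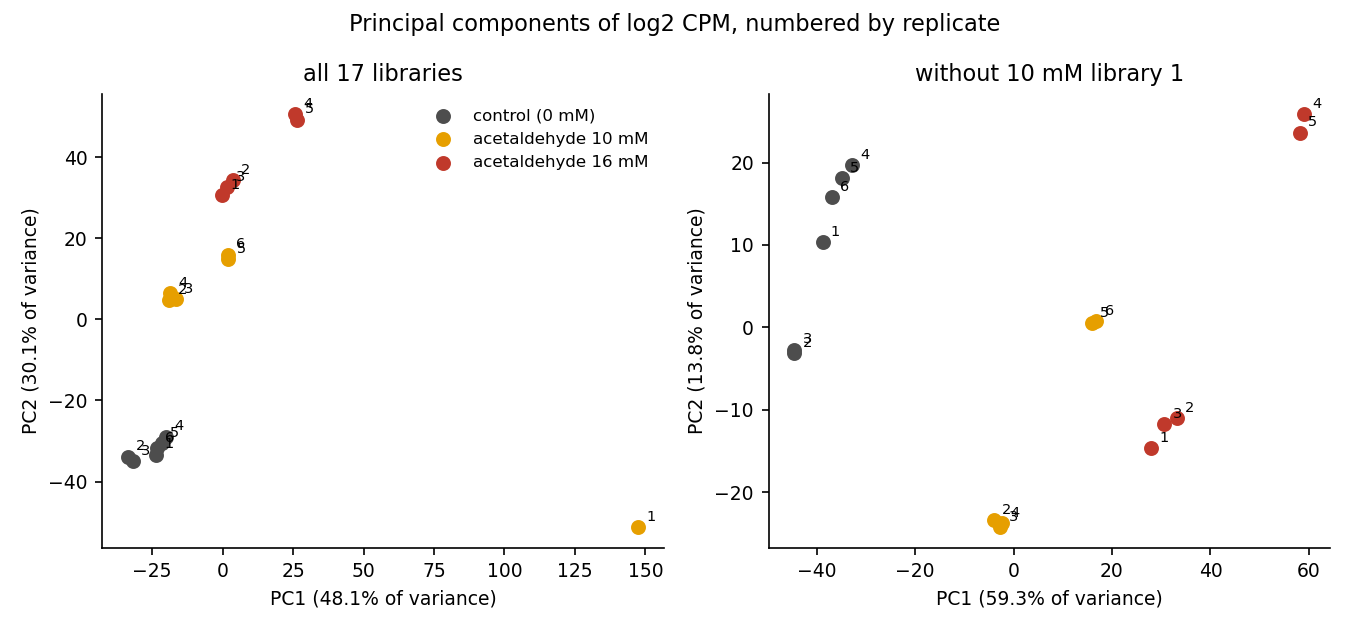
Principal components of log2 CPM (normalized counts), each point a library numbered by its replicate, with all 17 libraries on the left and 10 mM library 1 left out on the right. On the left the axis of largest variance (48.1%) sets 10 mM library 1 apart from the other 16 libraries.

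The comparison of 16 mM with control asked which transcripts the higher dose moved, and the series title names PI3K/AKT and MAPK/ERK signalling, cell damage and genotoxicity as its subjects. Among the gene lists fixed in advance, 13 of 20 heat shock genes, 14 of 26 NRF2 targets and 10 of 19 ERK-induced genes were higher at 16 mM, and 6 of 8 fibroblast markers were lower. HSPA6, a strictly inducible member of the HSP70 chaperone family (chromosome 1, 161524540 to 161527283, GRCh38.p13), rose 59.5-fold, from 0.190 ± 0.0974 FPKM (SD, n = 6) to 11.1 ± 4.25 FPKM (n = 5). FOSL1, which encodes a subunit of the transcription factor AP-1 (chromosome 11, 65892049 to 65900545), rose 14.8-fold, from 3.20 ± 1.59 to 45.8 ± 16.1 FPKM. PARD3B, a cell polarity scaffold (chromosome 2, 204544513 to 205620162), fell to 0.0129 of its control level, from 6.95 ± 1.69 to 0.0840 ± 0.0207 FPKM. In total 2169 genes rose and 2270 fell by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (its adjusted p is called edgeR adjusted p from here on), and 407 of the risen and 916 of the fallen genes changed at least 2-fold.

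Among the genes with the largest rises that had no overlap between the libraries of both groups, HSPA6 changed by 5.90 ± 1.80 on the log2 scale (estimate ± SE, edgeR adjusted p = 0.0172). DMBT1, a secreted scavenger receptor of mucosal surfaces, rose by 4.72 ± 0.31 (edgeR adjusted p = 1.55e-08). OSGIN1, a target of the oxidative stress regulator NRF2, rose by 4.24 ± 0.71, and IL11, a cytokine of the interleukin-6 family, rose by 3.35 ± 0.44. HES1, a transcriptional repressor downstream of Notch, rose by 3.27 ± 0.90. HSPA1A and HSPA1B rose by 4.01 ± 1.01 and 3.48 ± 0.96. They are near-identical copies of the inducible HSP70 gene, so the division of reads between them is uncertain. Among genes with at least 5 FPKM in the higher group and no such overlap, the largest falls were those of PARD3B (-6.28 ± 0.38, edgeR adjusted p = 7.93e-09), the adhesion molecules SDK1 (-5.19 ± 0.32) and NEGR1 (-4.33 ± 0.61), the pyrimidine-degrading enzyme DPYD (-3.70 ± 0.34), the membrane mucin MUC1 (-3.68 ± 0.32), the cytoskeletal adaptor SORBS2 (-3.56 ± 0.37), cardiac troponin T, TNNT2 (-3.52 ± 0.54), and the chloride channel ANO2 (-3.48 ± 0.38).

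Of the heat shock list, 13 of 20 members rose, 0 fell and 7 did not pass. For heat shock, 14 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 19 and 0. Its examples were HSPA1A, HSPA1B and HSPH1, the last a co-chaperone of HSP70 that rose by 2.3 ± 0.40, from 45.1 ± 8.98 to 225 ± 63.3 FPKM. The set test with a preset correlation ranked this list above other genes (camera adjusted p = 5.93e-06, and adjusted p = 0.922 with an estimated correlation). Of the NRF2 targets, 14 of 26 members rose, 2 fell and 10 did not pass, with camera adjusted p = 0.00111, and adjusted p = 0.922 with an estimated correlation. For NRF2 targets, 14 were higher and 2 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 16 and 2. The glutathione synthesis gene GCLM rose by 1.69 ± 0.20, the sulfiredoxin gene SRXN1 by 1.57 ± 0.27 and the ferritin light chain gene FTL by 1.51 ± 0.25. Of the cholesterol synthesis genes, 11 of 23 members rose, 1 fell and 11 did not pass, with camera adjusted p = 0.00790, adjusted p = 0.922 with an estimated correlation and adjusted p = 0.0752 without 10 mM library 1. For cholesterol synthesis genes, 11 were higher and 1 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 13 and 3. The mevalonate pathway enzymes IDI1 and HMGCS1 rose by 1.62 ± 0.26 and 1.47 ± 0.41. Their control levels were uneven: HMGCS1 stood at 15.1, 13.7, 12.8, 59.1, 57.2 and 37.1 FPKM in control libraries 1 to 6 and at 101.5, 96.66, 102.4, 75.49 and 72.94 FPKM in 16 mM libraries 1 to 5, and IDI1 at 30.8, 24.8, 23.3, 62.5, 63.0 and 49.6 and at 128, 131, 139, 138 and 138 FPKM. The size of these rises therefore depends on which control libraries are compared, and with close libraries summed HMGCS1 did not pass.

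Of the ribosome biogenesis list, 7 of 26 members rose, 0 fell and 19 did not pass, among them the nucleolar protein genes GNL3 (1.18 ± 0.25) and NOP2 (1.09 ± 0.33) (camera adjusted p = 0.00790, and adjusted p = 0.922 with an estimated correlation). For ribosome biogenesis, 7 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 19 and 1. Of the autophagy and lysosome list, 11 of 25 members rose, 1 fell and 13 did not pass, with camera adjusted p = 0.00822, and adjusted p = 0.922 with an estimated correlation. For autophagy and lysosome, 12 were higher and 1 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 16 and 3. SQSTM1, which encodes the cargo receptor p62, rose by 1.57 ± 0.34. Of the hypoxia and glycolysis list, 10 of 25 members rose, 2 fell and 13 did not pass, with camera adjusted p = 0.0294, adjusted p = 0.922 with an estimated correlation and adjusted p = 0.0542 without 10 mM library 1. For hypoxia and glycolysis, 10 were higher and 3 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 14 and 3. NDRG1 rose by 1.72 ± 0.24. Of the proteasome subunits, 4 of 27 members rose, 0 fell and 23 did not pass, with camera adjusted p = 0.0887, or, without 10 mM library 1, adjusted p = 0.0121 and adjusted p = 0.902 with an estimated correlation. For proteasome subunits, 0 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 17 and 0.

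Of the p53 targets, 7 of 24 members rose, 0 fell and 17 did not pass, with camera adjusted p = 0.217. For p53 targets, 7 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 12 and 3. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases also called p21, rose by 0.90 ± 0.31 (edgeR adjusted p = 0.0308). Its call was lost without any 1 of control libraries 4 to 6 or 16 mM libraries 1 to 3 (edgeR adjusted p of 0.0609 to 0.0683). It stood at 165, 157, 158, 86.7 and 93.6 FPKM in 16 mM libraries 1 to 5, against 84.52, 84.18, 86.73, 56.45, 56.38 and 57.85 FPKM in control libraries 1 to 6. Whether it rose in 16 mM libraries 4 and 5 therefore depends on which control libraries are compared. The kinase gene PLK3 rose by 1.41 ± 0.32. Of the Fanconi anaemia and crosslink repair list, 3 of 25 members rose, 5 fell and 17 did not pass, with camera adjusted p = 0.450. For Fanconi anaemia and crosslink repair, 3 were higher and 5 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 6 and 12. Of the enzymes of aldehyde and alcohol metabolism, 3 of 17 members rose, 6 fell and 8 did not pass, with camera adjusted p = 0.340. For enzymes of aldehyde and alcohol metabolism, 4 were higher and 6 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 5 and 10. ALDH3A1 fell from 1.54 ± 0.481 to 0.360 ± 0.0579 FPKM (log2 change -2.18 ± 0.29), ALDH1A1 from 2.17 ± 0.332 to 0.718 ± 0.504 FPKM (-1.61 ± 0.36), and ALDH2, the mitochondrial enzyme that oxidises acetaldehyde, from 5.01 ± 0.951 to 3.78 ± 0.230 FPKM (-0.38 ± 0.10). ALDH2 stood at 5.23, 5.77, 6.4, 4.26, 4.02 and 4.36 FPKM in control libraries 1 to 6 and at 3.9, 3.56, 3.66, 3.64 and 4.12 in 16 mM libraries 1 to 5. The size of its fall therefore depends on which control libraries are compared.

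Several genes used as markers of fibroblasts were expressed in these epithelial cells and were lower at 16 mM. Of the fibroblast markers, 0 of 8 members rose, 6 fell and 2 did not pass, with camera adjusted p = 0.00224, and adjusted p = 0.0797 with an estimated correlation. For fibroblast markers, 0 were higher and 6 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 0 and 7. The surface protease gene FAP fell by 2.07 ± 0.42, the growth factor receptor gene PDGFRB by 1.88 ± 0.42 and the microfibril protein gene MFAP4 by 1.87 ± 0.30 on the log2 scale. Of the replication-dependent histones, 0 of 5 members rose, 3 fell and 2 did not pass. For replication-dependent histones, 0 were higher and 3 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 0 and 5. Their transcripts mostly lack a poly-A tail, so poly-A enriched libraries hold them in part. Of the glutathione enzymes and thiol defence genes, 0 of 25 members rose, 5 fell and 20 did not pass, with MSRA, a methionine sulfoxide reductase, at -3.04 ± 0.66. For glutathione enzymes and thiol defence genes, 0 were higher and 4 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 5 and 15.

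Members of the pathways in the series title changed in both directions at 16 mM. Over all tested genes 4439 of 12564 were called, and the share called was smaller in both title lists. Without 10 mM library 1, 8271 of 12545 genes were called, a smaller share than in the PI3K-AKT list and about that of the MAPK-ERK list. Of the PI3K-AKT components, 2 of 28 members rose, 6 fell and 20 did not pass, with camera adjusted p = 0.684. For PI3K-AKT components, 2 were higher and 5 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 8 and 14. IRS2, an adaptor between the insulin receptor and PI3K, rose by 1.10 ± 0.12 (edgeR adjusted p = 3.86e-06). INPP4B, a phosphatase that removes a PI3K product, fell by 1.57 ± 0.15 (edgeR adjusted p = 7.14e-07). Its gene spans 869 kb, and its fall is near the median of genes over 400 kb at this dose (-1.48 without 10 mM library 1). IRS1 fell by 0.90 ± 0.25. AKT1 stood at 0.19 ± 0.09 (edgeR adjusted p = 0.123) and PIK3CA at -0.10 ± 0.12 (edgeR adjusted p = 0.565). The list's count of changed members was 5 without control library 6 and also 5 without 16 mM library 4 or 16 mM library 5.

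Of the MAPK-ERK cascade components, 4 of 22 members rose, 3 fell and 15 did not pass, with camera adjusted p = 0.824. For MAPK-ERK cascade components, 4 were higher and 3 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 7 and 7. The median member stood at 0.03 and the mean at -0.06, while the set test pointed up. The kinase gene MAP2K1 (MEK1) rose by 0.98 ± 0.13, whereas the receptor gene EGFR fell by 0.99 ± 0.24 and ARAF by 0.76 ± 0.12 on the log2 scale. MAPK3 (ERK1) stood at -0.09 ± 0.13 (edgeR adjusted p = 0.651). Of the genes that ERK activity is known to induce, 10 of 19 members rose, 0 fell and 9 did not pass, with camera adjusted p = 2.37e-05, and adjusted p = 0.269 with an estimated correlation. For ERK-induced genes, 11 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 13 and 0. Besides FOSL1 (3.89 ± 0.76), these included the ERK phosphatase genes DUSP5 (2.84 ± 0.59) and DUSP6 (2.20 ± 0.42), the feedback inhibitor SPRY4 (2.70 ± 0.28) and the transcription factor ETV4 (2.64 ± 0.23). Cyclin D1, CCND1, rose by 1.80 ± 0.30.

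Without 10 mM library 1, which is not part of the comparison but shares its estimate of spread, 4232 genes rose and 4039 fell between control and 16 mM, 441 and 950 of them at least 2-fold, and 4433 of the 4439 calls were shared with the same sign. A fit of these groups alone called 7979 genes. With a preset correlation camera called 8 of 45 lists (7 without 10 mM library 1, 6 of them shared), but 88 of 100 splits of the same libraries gave at least 8, and with an estimated correlation no list was called (0 of 45; 3 at an unadjusted p under 0.05; fry called 12). The authors' deposited table holds 8316 genes with a q-value under 0.05 for this comparison (4126 higher and 4190 lower), of which 4434 were among the edgeR calls with the same sign.

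**Figure D2:**
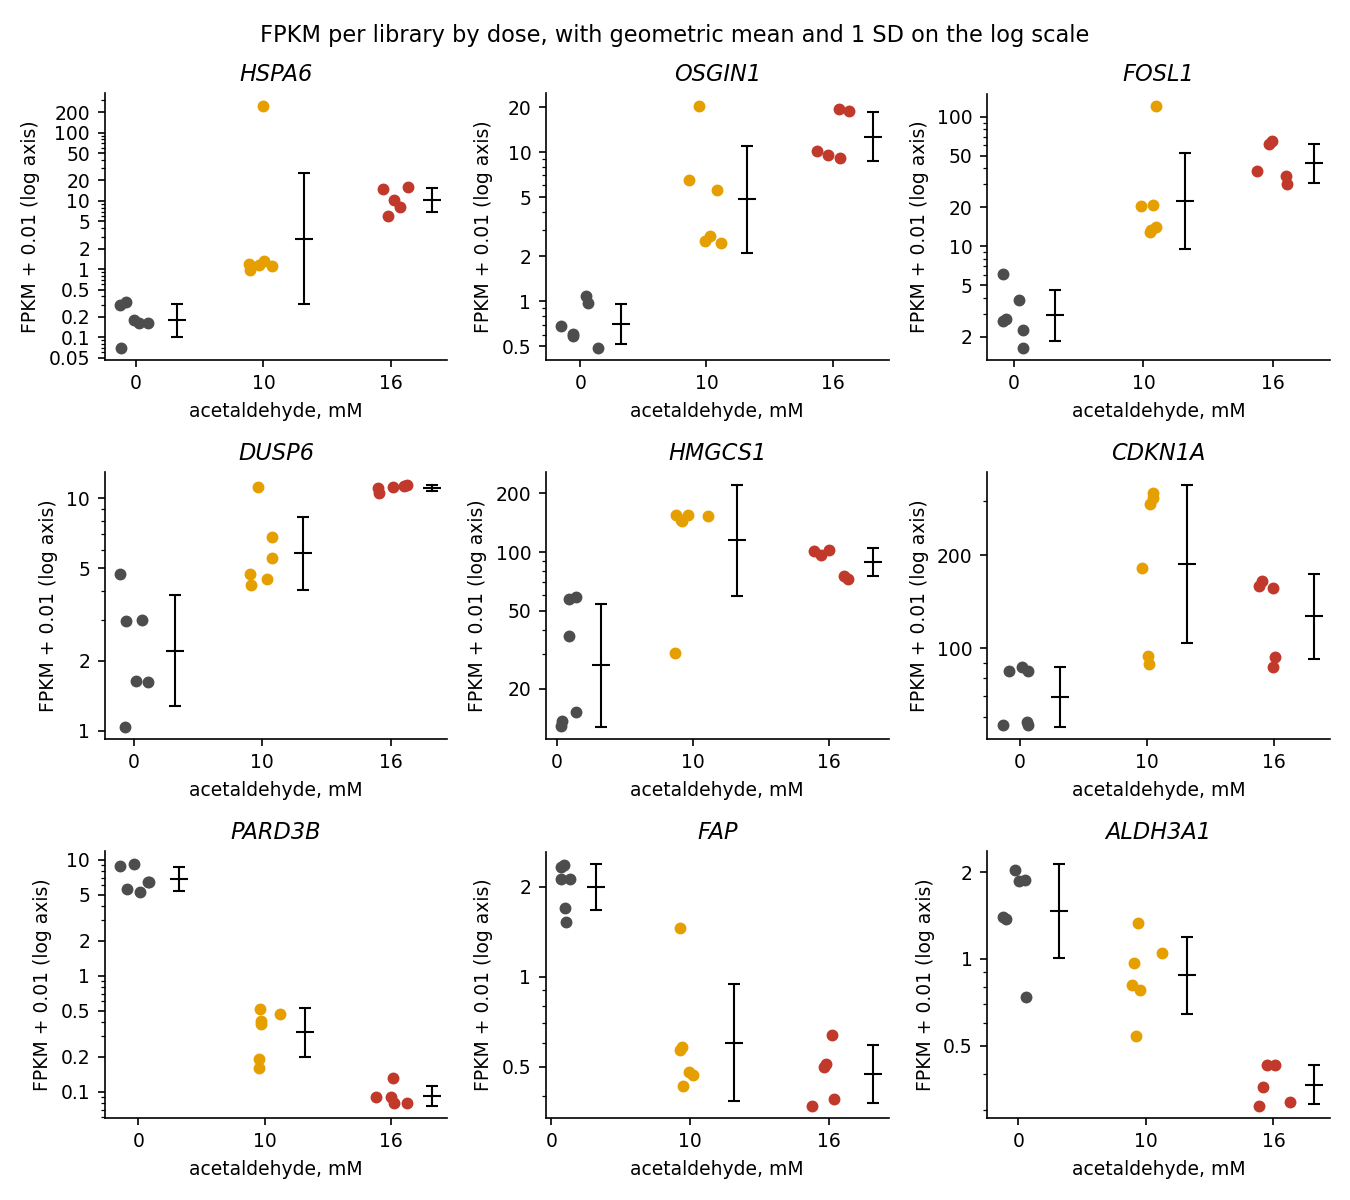
FPKM of 9 genes (plus 0.01, log axis) against acetaldehyde dose in mM, each point 1 library, with the geometric mean and 1 SD on the log scale beside each group (n = 6, 6 and 5). HSPA6 is 251 FPKM in 10 mM library 1 and 1.13 FPKM on average in the other 5 libraries at 10 mM, while PARD3B is lower than control in every treated library.

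The comparison of 10 mM with control asked the same of the lower dose. At 10 mM 15 of 20 heat shock genes, 18 of 26 NRF2 targets, 15 of 23 cholesterol synthesis genes and 9 of 19 ERK-induced genes were higher, and 5 of 8 fibroblast markers were lower. For the stress genes the group mean rested on 10 mM library 1: HSPA6 stood at 251 FPKM in that library and at 1.13 ± 0.117 FPKM (SD, n = 5) in the other 10 mM libraries, against 0.190 ± 0.0974 FPKM (n = 6) in control. HMGCS1, which starts the mevalonate pathway, stood at 30.3 FPKM in library 1 and at 150.4 ± 4.81 FPKM in the others, against 32.5 ± 21.8 in control. By edgeR's quasi-likelihood test 1182 genes rose and 1169 fell, 295 and 334 of them at least 2-fold.

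With all libraries, the largest rises with at least 5 FPKM in the higher group and no overlap between the groups were those of HSPA6 (8.70 ± 1.91 on the log2 scale, edgeR adjusted p = 0.00480), HSPA1A (5.08 ± 1.04), HSPA1B (4.95 ± 1.01), the heme-degrading enzyme gene HMOX1 (4.55 ± 1.09), FOSL1 (4.03 ± 0.75), HES1 (3.74 ± 0.89), OSGIN1 (3.73 ± 0.69) and the transcription factor gene SNAI1 (3.33 ± 0.72). With that library left out the same genes stood at 2.57 ± 0.38 (edgeR adjusted p = 5.19e-05), 2.31 ± 0.34, 2.22 ± 0.29, 1.43 ± 0.39, 2.36 ± 0.30, 1.4 ± 0.20, 2.46 ± 0.38 and 1.69 ± 0.23, respectively, and each kept its call. Within the same limits, the largest falls were those of PARD3B (-4.04 ± 0.30, edgeR adjusted p = 3.19e-07), SDK1 (-3.75 ± 0.27), NEGR1 (-3.43 ± 0.54) and TNNT2 (-2.64 ± 0.48). They were followed by the complement gene C4B (-2.35 ± 0.45), which has a near-identical copy and is uncertain for that reason, the inhibin subunit INHBE (-2.3 ± 0.61), the transporter ABCA8 (-2.05 ± 0.39) and the microfibril component FBN2 (-2.03 ± 0.15). Without 10 mM library 1 these genes stood at -4.28 ± 0.24 (edgeR adjusted p = 1.29e-09), -4.06 ± 0.15, -4.43 ± 0.29, -3.14 ± 0.42, -2.32 ± 0.47, -2.21 ± 0.57, -1.83 ± 0.27 and -1.92 ± 0.10, respectively, each still called. NEGR1 stood at 3.86 FPKM in that library and 0.278 ± 0.203 FPKM in the others.

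Of the heat shock list, 15 of 20 members rose, 0 fell and 5 did not pass, with camera adjusted p = 2.31e-09, and adjusted p = 0.484 with an estimated correlation. For heat shock, 19 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 15 and 0. DNAJB1, a co-chaperone of HSP70, rose by 2.84 ± 0.68 (1.10 ± 0.16 without 10 mM library 1). Of the NRF2 targets, 18 of 26 members rose, 3 fell and 5 did not pass, with camera adjusted p = 3.04e-08, and adjusted p = 0.256 with an estimated correlation. For NRF2 targets, 20 were higher and 3 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 21 and 3. FTL rose by 2.09 ± 0.25 and the quinone reductase gene NQO1 by 1.79 ± 0.32. Of the cholesterol synthesis genes, 15 of 23 members rose, 0 fell and 8 did not pass, with camera adjusted p = 2.52e-10, and adjusted p = 0.400 with an estimated correlation. For cholesterol synthesis genes, 19 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 18 and 0. HMGCS1 rose by 2.04 ± 0.41, MSMO1 by 1.71 ± 0.29 and IDI1 by 1.68 ± 0.25. MSMO1 too was uneven in control, at 37.2, 28.9, 28.4, 93.9, 92.5 and 73.0 FPKM in libraries 1 to 6, and with close libraries summed HMGCS1, MSMO1 and IDI1 did not pass. Of the proteasome subunits, 9 of 27 members rose, 0 fell and 18 did not pass, with camera adjusted p = 9.93e-06, and adjusted p = 0.700 with an estimated correlation. For proteasome subunits, 22 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 12 and 0. PSMA1 rose by 1.15 ± 0.30 (0.65 ± 0.12 without 10 mM library 1). Of the ribosome biogenesis list, 7 of 26 members rose, 0 fell and 19 did not pass, with camera adjusted p = 5.81e-04, adjusted p = 0.700 with an estimated correlation and adjusted p = 0.0895 without 10 mM library 1. For ribosome biogenesis, 9 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 8 and 3. Of the autophagy and lysosome list, 6 of 25 members rose, 0 fell and 19 did not pass, with camera adjusted p = 0.0133, adjusted p = 0.668 with an estimated correlation and adjusted p = 0.164 without 10 mM library 1. For autophagy and lysosome, 6 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 9 and 3. Of the hypoxia and glycolysis list, 6 of 25 members rose, 0 fell and 19 did not pass, with camera adjusted p = 9.91e-04, adjusted p = 0.557 with an estimated correlation and adjusted p = 0.0563 without 10 mM library 1. For hypoxia and glycolysis, 9 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 7 and 0.

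Of the p53 targets at 10 mM, 10 of 24 members rose, 0 fell and 14 did not pass, with camera adjusted p = 2.63e-04, and adjusted p = 0.668 with an estimated correlation. For p53 targets, 11 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 16 and 1. CDKN1A rose by 1.75 ± 0.30 (edgeR adjusted p = 8.38e-04), from 71.0 ± 15.5 to 214 ± 106 FPKM, and BTG2, an antiproliferative p53 target, rose by 1.54 ± 0.36. MDM2, the ubiquitin ligase that degrades p53, rose by 1.21 ± 0.41 (edgeR adjusted p = 0.0493), but the call was lost without any 1 of control libraries 1 to 6, 10 mM libraries 2 to 4 or 16 mM libraries 1 to 5 (edgeR adjusted p of 0.0542 to 0.0938). These genes differed between the libraries of the group. In 10 mM libraries 1 to 6, CDKN1A stood at 182, 293, 317, 306, 94.6 and 88.7 FPKM, BTG2 at 4.29, 34.4, 35.4, 39.7, 9.86 and 10.4 FPKM and MDM2 at 3.16, 59.9, 59.8, 66.4, 20.7 and 21.1 FPKM. In control libraries 1 to 6, CDKN1A stood at 84.52, 84.18, 86.73, 56.45, 56.38 and 57.85 FPKM and MDM2 at 17.25, 21.11, 19.47, 13.88, 13.57 and 15.53 FPKM. BTG2 lay at 6.55 to 9.25 FPKM in control. How far CDKN1A and MDM2 rose in 10 mM libraries 5 and 6 therefore depends on which control libraries are compared. Of the Fanconi anaemia and crosslink repair list, 1 of 25 members rose, 8 fell and 16 did not pass, with camera adjusted p = 0.00729, and adjusted p = 0.416 with an estimated correlation. For Fanconi anaemia and crosslink repair, 1 were higher and 8 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 1 and 13. The core complex gene FANCE fell by 0.71 ± 0.12 and the recombination gene XRCC2 by 0.70 ± 0.13, while UBE2T, the ubiquitin-conjugating enzyme of the pathway, rose by 0.64 ± 0.15. Of the enzymes of aldehyde and alcohol metabolism, 3 of 17 members rose, 1 fell and 13 did not pass, with camera adjusted p = 0.215. For enzymes of aldehyde and alcohol metabolism, 5 were higher and 1 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 4 and 3. ALDH2 stood at -0.07 ± 0.09 (edgeR adjusted p = 0.631). Of the fibroblast markers, 0 of 8 members rose, 5 fell and 3 did not pass, with camera adjusted p = 0.00912, and adjusted p = 0.256 with an estimated correlation. For fibroblast markers, 0 were higher and 5 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 1 and 6. FAP fell by 1.34 ± 0.38 (-2.04 ± 0.17 without 10 mM library 1), a call lost without 10 mM library 6 (edgeR adjusted p = 0.0514).

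Over all tested genes, 2351 of 12564 were called at 10 mM, or 5670 of 12545 without 10 mM library 1. Of the PI3K-AKT components at 10 mM, 0 of 28 members rose, 4 fell and 24 did not pass, with camera adjusted p = 0.169. For PI3K-AKT components, 0 were higher and 4 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 7 and 8. Among the members that fell were IRS1 (-1.0 ± 0.24), INPP4B (-0.85 ± 0.14) and PIK3CA (-0.39 ± 0.11). AKT1 stood at 0.22 ± 0.09 (edgeR adjusted p = 0.0851). Of the MAPK-ERK cascade components, 3 of 22 members rose, 2 fell and 17 did not pass, with camera adjusted p = 0.879. For MAPK-ERK cascade components, 3 were higher and 2 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 5 and 4. MAPK3 rose by 0.50 ± 0.13, MAP2K1 by 0.49 ± 0.12 and the kinase gene RPS6KA1 by 0.28 ± 0.08, the last call being lost without control library 2 or 3 (edgeR adjusted p of 0.0524 to 0.0526). In contrast, EGFR fell by 0.87 ± 0.23 and RASA1, which switches RAS off, by 0.57 ± 0.13. Of the genes that ERK activity is known to induce, 9 of 19 members rose, 0 fell and 10 did not pass, with camera adjusted p = 4.25e-05, and adjusted p = 0.256 with an estimated correlation. For ERK-induced genes, 9 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 10 and 0. DUSP5 rose by 2.45 ± 0.57, ETV4 by 2.35 ± 0.23 and DUSP6 by 1.66 ± 0.41. Without 10 mM library 1 these stood at 1.23 ± 0.23, 2.19 ± 0.19 and 1.07 ± 0.26.

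Without 10 mM library 1, 2816 genes rose and 2854 fell at 10 mM, 220 and 350 of them at least 2-fold, and 2335 of the 2351 calls were shared with the same sign. Without control library 1, 2 or 3, 745, 738 or 749 genes rose. On the FPKM values, limma called 668 genes higher and 1136 lower (37.0% higher, against 50.3% in the counts), with the median of all genes at -0.11 on the log2 scale in place of 0.05. Camera with a preset correlation called 13 of 45 lists (12 without 10 mM library 1, 8 of them shared), a number that 99 of 100 splits of the same libraries reached, and with an estimated correlation it called none (0 of 45; 5 at an unadjusted p under 0.05; fry called 8). The authors' deposited table holds 2554 genes with a q-value under 0.05 (1282 higher and 1272 lower), 2143 of them among the edgeR calls with the same sign.

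**Figure D3:**
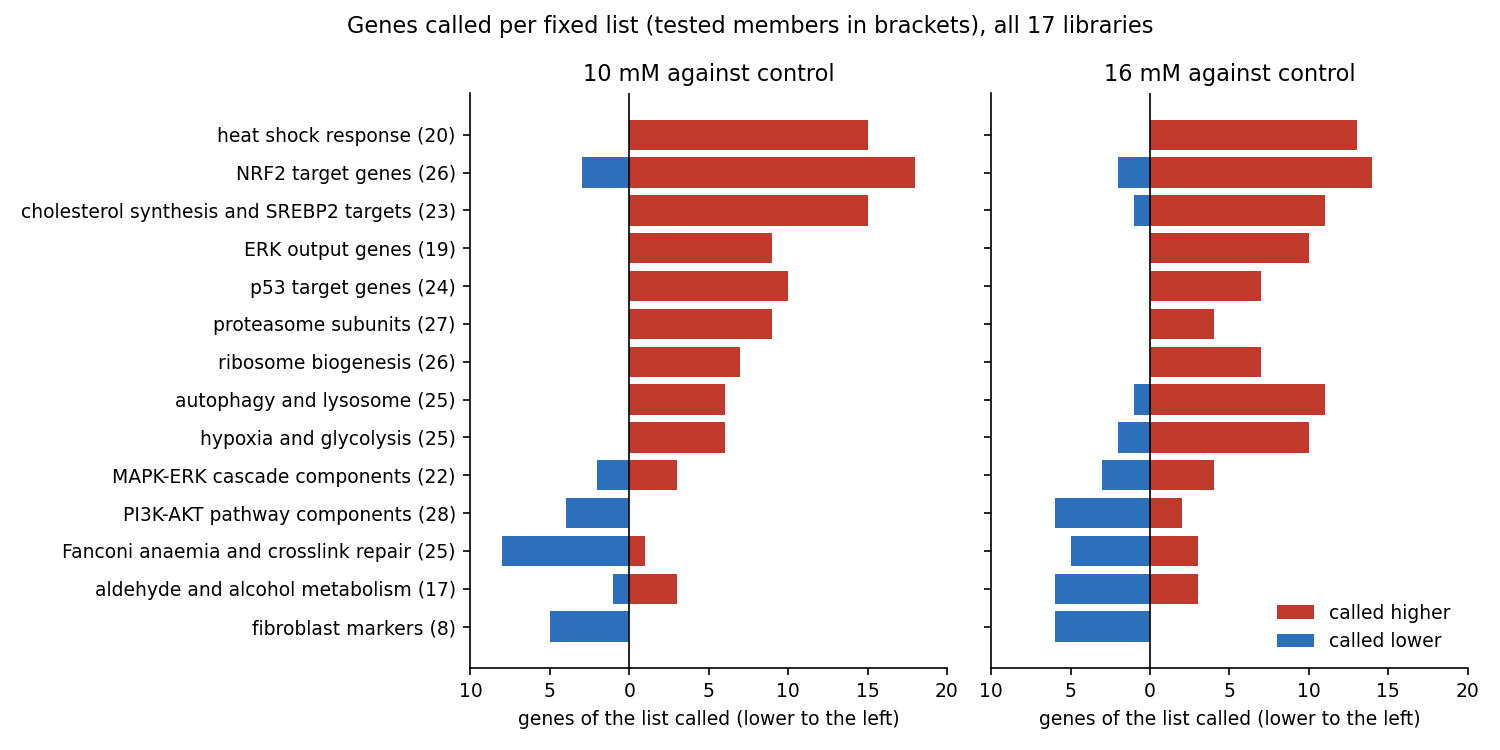
Number of genes of 14 fixed lists called higher (to the right) or lower (to the left) at 10 mM and at 16 mM against control, with the tested members of each list in brackets. The heat shock list has 15 of 20 members higher at 10 mM and 13 at 16 mM, and the fibroblast markers have 5 and 6 of 8 lower.

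At both doses 836 genes rose and 967 fell, 1803 in the same direction, and 1 gene was called in opposite directions. Independent lists of the same sizes would share 415 genes. Unchanged groups simulated against the same controls had too few calls to share any (0, mean of 20 simulations), which is no benchmark for the overlap. The log2 changes correlated across genes at r = 0.762, against r = 0.470 in the simulations. Genes are not independent replicates. The covariance was 0.345, or 0.313 above the simulated covariance, which estimates the shared effect. The overlap without 10 mM library 1 was 4630 genes, with 1869 for independent lists, and 81 genes were then called in opposite directions. With odd controls serving 10 mM and even controls serving 16 mM, it was 232 genes with all treated libraries and 3389 without 10 mM library 1. With the controls exchanged, it was 3372 without that library. PARD3B, SDK1 and NEGR1 were among the genes that fell at both doses, and FOSL1, OSGIN1 and HSPA6 among those that rose.

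The comparison of 16 mM with 10 mM tested the difference between the doses itself. At 16 mM the transcript of POLR2A, the largest subunit of RNA polymerase II, was higher than at 10 mM (153 ± 39.4 against 49.6 ± 22.6 FPKM; SD, n = 5 and n = 6), as were 4 of 19 ERK-induced genes, while 7 of 17 enzymes of aldehyde and alcohol metabolism were lower. POLR2A stood at 6.78, 50.23, 53.01, 50.92, 69.41 and 67.21 FPKM in 10 mM libraries 1 to 6, so 10 mM library 1 adds to this difference and to the SD. In total 840 genes were higher and 937 lower by edgeR's quasi-likelihood test, 40 and 275 of them at least 2-fold. POLR2A rose by 1.63 ± 0.31 (edgeR adjusted p = 0.00357), the lipid transfer protein gene GRAMD1B by 1.23 ± 0.23, DMBT1 by 1.18 ± 0.26, SPRY4 by 1.13 ± 0.27, TSPYL2 by 1.11 ± 0.15, NDRG1 by 1.09 ± 0.24 and the mRNA export factor gene NXF1 by 1.05 ± 0.23. SHISA2 rose by 1.47 ± 0.41, a call lost without any 1 of 10 mM libraries 2 and 3 or 16 mM libraries 4 and 5 (edgeR adjusted p of 0.0502 to 0.0890). The polarity protein gene PARD6A fell by 1.71 ± 0.23 (edgeR adjusted p = 4.54e-04) and the mitochondrial ribosomal protein gene MRPL54 by 2.33 ± 0.56, or -1.20 ± 0.16 without 10 mM library 1.

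The other large falls rested in part on 10 mM library 1. They were those of the metallothionein gene MT1X (-2.81 ± 0.85), which has close paralogs, the cytochrome oxidase assembly gene PET100 (-1.87 ± 0.57), CHCHD5 (-1.80 ± 0.51), the complex I subunit gene NDUFB1 (-1.75 ± 0.54), ANAPC15 (-1.73 ± 0.48) and HSD17B8 (-1.71 ± 0.50). Without that library they stood at -0.66 ± 0.26, -0.70 ± 0.18, -0.76 ± 0.13, -0.62 ± 0.14, -0.82 ± 0.16 and -0.72 ± 0.12, respectively. The calls of MT1X and PET100 were lost without any 1 of 16 mM libraries 1 to 5 (edgeR adjusted p of 0.0613 to 0.0960 and 0.0668 to 0.0935), those of CHCHD5 and ANAPC15 without any 1 of 16 mM libraries 2 to 5 (0.0586 to 0.0760 and 0.0535 to 0.0571), that of HSD17B8 without any 1 of 16 mM libraries 1, 2, 4 and 5 (0.0580 to 0.0863) and that of NDUFB1 without any 1 of control libraries 1, 4, 5 and 6 or 16 mM libraries 1 to 5 (0.0502 to 0.0882).

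Of the genes that ERK activity is known to induce, 4 of 19 members rose, 0 fell and 15 did not pass between the doses, with camera adjusted p = 0.00667, and adjusted p = 0.890 with an estimated correlation. For ERK-induced genes, 6 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 9 and 0. They were SPRY4, ETV5 (0.91 ± 0.28), SPRED1 (0.78 ± 0.23) and EPHA2 (0.47 ± 0.14). The call of ETV5 was lost without any 1 of control library 6, 10 mM libraries 2, 3, 4 and 6 or 16 mM libraries 1 to 5 (edgeR adjusted p of 0.0501 to 0.102), that of SPRED1 without any 1 of 10 mM library 3 or 16 mM libraries 4 and 5 (0.0506 to 0.0938) and that of EPHA2 without any 1 of control library 6, 10 mM libraries 2 to 6 or 16 mM libraries 2, 4 and 5 (0.0501 to 0.0986). DUSP6 stood at 0.53 ± 0.41 (edgeR adjusted p = 0.382), and at 1.12 ± 0.26 (edgeR adjusted p = 0.00239) without 10 mM library 1. Of the enzymes of aldehyde and alcohol metabolism, 0 of 17 members rose, 7 fell and 10 did not pass, with camera adjusted p = 4.53e-04, and adjusted p = 0.890 with an estimated correlation. For enzymes of aldehyde and alcohol metabolism, 0 were higher and 9 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 1 and 8. ALDH3A1 fell by 1.55 ± 0.30, ALDH3B1 by 0.79 ± 0.14 and ALDH1A1 by 1.18 ± 0.36, the last call being lost without any 1 of 10 mM libraries 2 to 4 or 16 mM libraries 2, 4 and 5 (edgeR adjusted p of 0.0593 to 0.0986). Of the histones, 0 of 5 members rose, 3 fell and 2 did not pass, with camera adjusted p = 0.00279, and adjusted p = 0.890 with an estimated correlation. For histones, 0 were higher and 5 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 0 and 4. H2AC6 fell by 2.07 ± 0.48.

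Over all tested genes, 1777 of 12564 were called between the doses, or 5537 of 12545 without 10 mM library 1. Of the PI3K-AKT components, 2 of 28 members rose, 2 fell and 24 did not pass between the doses, with camera adjusted p = 0.612. For PI3K-AKT components, 2 were higher and 2 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 7 and 10. The median member stood at -0.00 and the mean at -0.06, while the set test pointed up. IRS2 rose by 0.76 ± 0.12, INPP4B fell by 0.72 ± 0.15 and AKT2 fell by 0.36 ± 0.07. RPS6KB1 rose by 0.38 ± 0.12, a call lost without any 1 of control libraries 1 to 6, 10 mM libraries 2, 3, 5 and 6 or 16 mM libraries 1 to 5 (edgeR adjusted p of 0.0527 to 0.127). Of the MAPK-ERK cascade components, 2 of 22 members rose, 2 fell and 18 did not pass, with camera adjusted p = 0.610. For MAPK-ERK cascade components, 2 were higher and 2 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 5 and 8. The median member stood at 0.08 and the mean at -0.03, while the set test pointed up. MAP2K1 rose by 0.49 ± 0.13 and GRB2 by 0.35 ± 0.08, and ARAF fell by 0.70 ± 0.12 and MAPK3 by 0.59 ± 0.13. The call of MAP2K1 was lost without 16 mM library 4 or 5 (edgeR adjusted p of 0.0612 to 0.0648). Of the cholesterol synthesis genes, 0 of 23 members rose, 2 fell and 21 did not pass, with camera adjusted p = 0.0106, adjusted p = 0.890 with an estimated correlation and adjusted p = 0.0622 without 10 mM library 1. For cholesterol synthesis genes, 0 were higher and 1 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 0 and 8. LSS, an enzyme of the sterol branch, was among those that fell (-0.95 ± 0.30), a call lost without any 1 of control library 6, 10 mM libraries 2 to 6 or 16 mM libraries 1 to 5 (edgeR adjusted p of 0.0517 to 0.119). Of the heat shock list, 0 of 20 members rose, 0 fell and 20 did not pass, with camera adjusted p = 0.576, or, without 10 mM library 1, adjusted p = 0.00809 and adjusted p = 0.979 with an estimated correlation. For heat shock, 0 were higher and 0 lower when adjusted over the list alone, and over all genes without 10 mM library 1 these were 10 and 0. Its median member stood at -0.17 and the mean at -0.29, while the set test pointed up. HSPA1A stood at -1.07 ± 0.94 (edgeR adjusted p = 0.447), and at 1.71 ± 0.35 (edgeR adjusted p = 0.00104) without 10 mM library 1, which turned its direction. CDKN1A stood at -0.85 ± 0.31 (edgeR adjusted p = 0.0782).

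Without 10 mM library 1, 2916 genes were higher and 2621 lower at 16 mM than at 10 mM, 95 and 314 of them at least 2-fold (40 and 275 with it), all 1777 calls being shared with the same sign. Without 16 mM library 4 or 16 mM library 5 the count fell to 808 or 842. DESeq2's Wald test called 1159 genes higher and 1483 lower, 69 and 377 of them at least 2-fold, and edgeR without a filter on low counts gave 70 and 264 at least 2-fold. On the FPKM values limma called 761 genes higher and 489 lower (60.9% higher, against 47.3% in the counts), with the median of all genes at 0.10 in place of -0.06 on the log2 scale, and when libraries lying close together were summed, which left 2 sums per group, edgeR called 0 genes (2606 at an unadjusted p under 0.05). Camera with a preset correlation called 9 of 45 lists (also 9 without 10 mM library 1, 6 of them shared), a number that 95 of 100 splits reached, and with an estimated correlation none (0 of 45; 1 at an unadjusted p under 0.05; fry called 5). The authors' deposited table holds 1568 genes with a q-value under 0.05 (707 higher and 861 lower), 1390 of them among the edgeR calls with the same sign.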

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

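The tests of length, of response and of cell type for 10 mM library 1 were chosen only after its deviation had been seen. Of 42 groups of values checked for a sample far from the others, 12 held one, and in 11 of these the sample was 10 mM library 1. Chance gives about 1 in 20 for independent and normally spread values, which these are not. The genes checked are among those the text names, and the changes of some of them rest on 10 mM library 1. The counts, here and for the other named genes below, therefore describe that library and do not test it. The measure is the gap to the nearest other library as a share of the group's range. In 10 mM library 1 it was 0.77 for the total count (18809242 counts), 0.66 for genes detected (11716), 0.81 for the share of counts in the 10 highest genes (6.08%), 0.857 for the TMM factor (0.559) and 0.817 for the median FPKM (2.62).

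For single genes in 10 mM library 1 the measure was 0.999 for HSPA6 (251 FPKM, against 1.13 ± 0.117 in the other 10 mM libraries, SD, n = 5), 0.776 for OSGIN1 (20.4 against 3.96 ± 1.93 FPKM), 0.928 for FOSL1 (122 against 16.3 ± 3.92 FPKM), 0.628 for DUSP6 (11.1 against 5.14 ± 1.04 FPKM), 0.916 for HMGCS1 (30.3 against 150.4 ± 4.81 FPKM) and 0.854 for FAP (1.45 against 0.496 ± 0.0658 FPKM). In 16 mM library 3 it was 0.8 for PARD3B. Over the other genes named in the text, 48 of 285 groups held such a sample, in 46 of them 10 mM library 1.

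10 mM library 1 departed from its group with an SD across genes of 1.51 on the log2 scale, and its departures fell with transcript length (Spearman's rho of -0.573 across genes). A loss of long transcripts is argued against as the whole cause, since a trend on length and GC removed 33.3% of their variance and the SD after it was 1.23, against at most 0.37 in the other 16 libraries. RNA of secretory, ciliated, fibroblast, leukocyte or endothelial cells is argued against too, since among their markers that average under 1 FPKM elsewhere the highest median of any type was 0.2 FPKM. RNA of basal or squamous cells stays open: their 9 tested markers were higher by a median of 1.88 (1.85 after the trend), whereas the 8 markers on their list that average under 1 FPKM elsewhere had a median of 0.035 FPKM, with the keratin gene KRT16 at 13.9 FPKM. A stronger response to acetaldehyde stays open as well, because the corrected departures correlated with the change at 16 mM at r = 0.110 across genes, just above the bound under which it would have been argued against, and a separate handling of this sample was not tested.

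Heat shock genes were higher in 10 mM library 1 than in the other 10 mM libraries, by a median of 2.19 over 20 genes. Length and GC do not account for this alone: the median was 1.67 after the trend, above every one of 10000 random lists of the same size. An effect of acetaldehyde and a stress in handling were not tested for this list, since the group holds only 1 such library, and both stay open.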

How the results depend on the processing

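The block without 10 mM library 1 and the sums of close libraries were tests chosen only after the data had been seen. Unless named here, each alternative fit left each total count of genes, lists and pathways within 1.5 times, and the cause of the moves was not tested, except where fewer samples or groups entered by construction. Limma on log2(FPKM + 1), whose pseudocount shrinks changes of low genes, gave 244, 690 and 43 genes changed at least 2-fold for 10 mM, 16 mM and 16 mM against 10 mM (629, 1323 and 315 in the counts). Voom with library weights called 7517, 9201 and 7530 genes, 5931 at both doses, 22 PI3K-AKT and 16 MAPK-ERK members. Fits of only the groups compared called 1530, 7979 and 569 genes, 123 at least 2-fold between the doses, 21 PI3K-AKT and 13 MAPK-ERK members. With an estimated correlation, camera called 0 lists and 0 KEGG pathways in each comparison, where the preset one called 13, 8 and 9 lists and 38, 5 and 25 pathways. At an unadjusted p under 0.05 it gave 13, 3 and 5 pathways, and fry called 32, 67 and 13. By direction, the DESeq2 Wald test called 1483 genes lower between the doses (937 by edgeR). Genes at least 2-fold higher between the doses, 40 by edgeR, numbered 69 with that test, 70 without the filter, 79 with voom weights, 16 on log2(FPKM + 1), and 95 and 26 without 10 mM library 1 or 16 mM library 4. At 10 mM those at least 2-fold higher, 295 by edgeR, numbered 188 with the replicate block and 172 in the fit of only the groups compared, which called 696 genes higher (1182 by edgeR). Without the filter on low counts, 3 pathways were called at 16 mM. The number of genes with at least 1 FPKM differed by -200.1 between 16 mM and control (exact permutation test, adjusted p = 0.026), where that with at least 10 counts differed by -177.4 (adjusted p = 0.0843).

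Replicate numbers were not taken to pair the libraries, since this asked for every pair with the same number to have correlated deviations above 0.1. Of pairs with the same number 12 of 16 did (median 0.192, lowest -0.390), against 29 of 80 with other numbers (median -0.115), and 3 of 17 libraries correlated best with their own number. The numbers also run partly along the sets of close libraries, and this check does not separate these. The replicate block called 1824, 4153 and 1304 genes. The block without 10 mM library 1 called 5653, 8506 and 5881 genes, 4652 at both doses, 497 at least 2-fold between the doses, 23 PI3K-AKT and 14 MAPK-ERK members, and 6, 9 and 8 pathways. With close libraries summed (2 sums per group, without 10 mM library 1), 246 genes were called at 10 mM (55 higher and 191 lower), 176 of them at least 2-fold, 0 between the doses (0 at least 2-fold, 2606 at an unadjusted p under 0.05), 241 at both doses, and 7 pathways both at 10 mM and between the doses.

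With each library left out in turn, the genes called ranged from 1633 to 5670 at 10 mM, 3559 to 8271 at 16 mM and 808 to 5537 between the doses, and those at least 2-fold from 510 to 812, 1168 to 1431 and 145 to 421. The overlap of both doses ranged from 1346 to 4630 genes, the PI3K-AKT members from 5 to 22 and the MAPK-ERK members from 6 to 14. Called lists ranged from 12 to 15, 7 to 8 and 8 to 10, and pathways from 4 to 42, 5 to 5 and 10 to 42. The highest counts of genes called and the lowest pathway counts came without 10 mM library 1, whereas the highest counts at least 2-fold came without 10 mM library 2 (812), 16 mM library 1 (1431) and 10 mM library 6 (421), against 570, 1391 and 409 without 10 mM library 1. Between the doses, 16 mM libraries 4 and 5 set the low end (808 and 842 genes, 145 and 160 at least 2-fold), and pathways numbered 42, 39, 42 and 16 without 10 mM libraries 2, 3 and 4 and 16 mM library 3. Differences in genes detected ranged from -199 to -48.6, -211 to -131 and -128.8 to 24.0, and without 16 mM library 1 that at 16 mM (-211) passed, with an exact permutation test adjusted p = 0.0429.

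Named genes that did not pass and turned direction were HSPA1A, IL6 and MYC, and the cause was not tested. HSPA1A stood at -1.07 between the doses, at 1.52 with voom weights and at 1.79 with the block and without 10 mM library 1. With each library left out in turn it ranged from -1.32 to 1.71, the latter without 10 mM library 1. With voom weights at 16 mM, IL6 stood at 0.47 (limma adjusted p = 0.0367), in place of -0.24, and MYC at -0.34 (limma adjusted p = 0.0445), in place of 0.09. Of 144 values of named genes, 132 were called. 18 of these were lost without at least 1 library, 0 without 10 mM library 1, and 40 under at least 1 alternative fit chosen in advance. With close libraries summed, which leaves 2 sums per group and so less power, 63 were lost. Depth and spread limit small changes: in simulation 30% and 28% of 1.5-fold changes were recovered at 10 mM and 16 mM.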

Other observations

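The tests of KEGG zinc finger members, of span and of length were chosen only after the results had been seen, those of low expression, of single libraries and of other splits before. Of the apoptosis regulators, 9 higher and 1 lower of 28 (9 and 1 adjusted over the list alone, 13 and 8 over all genes without 10 mM library 1) were called at 16 mM (camera adjusted p = 0.190) and 5 higher and 3 lower of 28 (8 and 4 adjusted over the list alone, 10 and 5 over all genes without 10 mM library 1) at 10 mM (camera adjusted p = 0.0987), so camera did not call the list at either dose. Fry, which asks only whether the members move in 1 direction on balance, did call it as rising (fry adjusted p = 1.20e-07 and 9.67e-06). The death receptor gene TNFRSF10A rose by 1.39 ± 0.15 at 16 mM and 1.11 ± 0.15 at 10 mM. Of the NF-kB cytokines and chemokines, 6 higher and 1 lower of 19 (6 and 1 adjusted over the list alone, 8 and 3 over all genes without 10 mM library 1) were called at 16 mM (camera adjusted p = 0.150), and at 10 mM 4 higher and 2 lower of 19 (5 and 2 adjusted over the list alone, 6 and 2 over all genes without 10 mM library 1) (camera adjusted p = 0.169). At 16 mM the list held the interleukin gene IL11 at 3.35 ± 0.44 and RELB, a subunit of NF-kB, at 1.4 ± 0.24. The basal and squamous markers were divided at 16 mM, with 3 higher and 3 lower of 9 (3 and 3 adjusted over the list alone, 5 and 3 over all genes without 10 mM library 1): the keratin gene KRT17 rose by 1.90 ± 0.47 and the neurotrophin receptor gene NGFR by 2.00 ± 0.41, while the hemidesmosome integrin gene ITGB4 fell by 1.98 ± 0.22. Of the epithelial junction genes, 1 higher and 4 lower of 15 (1 and 4 adjusted over the list alone, 2 and 8 over all genes without 10 mM library 1) were called, with the desmosomal gene PKP2 at -1.74 ± 0.17.

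At 16 mM the DNA replication list had 1 higher and 3 lower of 26 (1 and 2 adjusted over the list alone, 2 and 14 over all genes without 10 mM library 1), and at 10 mM 0 higher and 2 lower of 26 (0 and 2 adjusted over the list alone, 0 and 13 over all genes without 10 mM library 1), with camera adjusted p = 0.495, or, without 10 mM library 1, adjusted p = 0.00238 and adjusted p = 0.783 with an estimated correlation. POLA1, a subunit of the replicative primase complex, fell by 1.43 ± 0.14 at 16 mM. The G2/M list had 1 higher and 1 lower of 26 (0 and 0 adjusted over the list alone, 4 and 3 over all genes without 10 mM library 1) at 16 mM. At the same dose nucleotide and base excision repair had 8 higher and 3 lower of 26 (8 and 6 adjusted over the list alone, 9 and 13 over all genes without 10 mM library 1), with the DNA glycosylase gene NEIL2 at 1.09 ± 0.13. The ATF4 targets had 2 higher and 7 lower of 24 (2 and 9 adjusted over the list alone, 7 and 12 over all genes without 10 mM library 1). FGF21, a secreted stress hormone, fell by 4.61 ± 0.64 and the transcription factor gene ATF5 rose by 1.26 ± 0.17. The stress kinase list had 6 higher and 3 lower of 20 (6 and 3 adjusted over the list alone, 13 and 4 over all genes without 10 mM library 1), with MAP2K3 at 2.04 ± 0.28, and the FOXO targets had 4 higher and 1 lower of 19 (4 and 0 adjusted over the list alone, 7 and 4 over all genes without 10 mM library 1), with KLF2 at 1.33 ± 0.27. Of the 40 anchor genes, 9 rose, 6 fell and 25 did not pass at 16 mM, and 10, 4 and 26 at 10 mM. Leaving out 10 mM library 1 made these 16, 12 and 12, and 14, 8 and 18. Among the anchors that did not pass at 16 mM were the crosslink repair gene FANCD2 (-0.24 ± 0.18), the proliferation marker MKI67 (-0.19 ± 0.26), MYC (0.09 ± 0.35) and the interleukin gene IL6 (-0.24 ± 0.33).

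Nuclear genes of mitochondrial respiration and ribosomal protein genes stood lower at 16 mM than at 10 mM as lists with all libraries, and most of this shift rested on 10 mM library 1. Of the nuclear-encoded genes of oxidative phosphorylation, 0 higher and 0 lower of 27 (0 and 0 adjusted over the list alone, 0 and 6 over all genes without 10 mM library 1) were called, with camera adjusted p = 4.53e-04, and adjusted p = 0.890 with an estimated correlation for a lower list. At 10 mM against control 2 higher and 0 lower of 27 (0 and 0 adjusted over the list alone, 6 and 3 over all genes without 10 mM library 1) were called, with the list higher (median 0.65, 0.10 without 10 mM library 1; camera adjusted p = 0.00119, adjusted p = 0.762 with an estimated correlation and adjusted p = 0.334 without 10 mM library 1). Once 10 mM library 1 was left out, the median member between the doses stood at -0.15, against -0.77 with it. Of the cytosolic ribosomal proteins, 0 higher and 0 lower of 28 (0 and 0 adjusted over the list alone, 0 and 0 over all genes without 10 mM library 1) were called between the doses, with camera adjusted p = 0.00279, adjusted p = 0.890 with an estimated correlation and adjusted p = 0.278 without 10 mM library 1. Their median was -0.96 (-0.09 without 10 mM library 1). The KEGG pathway named ribosome held 0 higher and 2 lower of 132 between the doses (camera adjusted p = 1.18e-05, adjusted p = 0.983 with an estimated correlation), and 11 higher and 17 lower without 10 mM library 1 (camera adjusted p = 0.354). Of the glutathione enzymes and thiol defence genes, 0 higher and 6 lower of 25 (0 and 8 adjusted over the list alone, 2 and 13 over all genes without 10 mM library 1) were called between the doses, with camera adjusted p = 4.53e-04, and adjusted p = 0.890 with an estimated correlation, and of the fatty acid synthesis genes 1 higher and 4 lower of 15 (1 and 7 adjusted over the list alone, 1 and 7 over all genes without 10 mM library 1), with camera adjusted p = 0.0116, and adjusted p = 0.890 with an estimated correlation. Of the immediate-early genes, 5 higher and 0 lower of 20 (5 and 0 adjusted over the list alone, 5 and 0 over all genes without 10 mM library 1) were called at 10 mM, with camera adjusted p = 0.0159, adjusted p = 0.668 with an estimated correlation and adjusted p = 0.117 without 10 mM library 1.

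Other lists passed camera's preset correlation only with or only without 10 mM library 1. At 10 mM the ATF4 targets had 2 higher and 3 lower of 24 (3 and 6 adjusted over the list alone, 2 and 14 over all genes without 10 mM library 1), with camera adjusted p = 0.0991, or, without 10 mM library 1, adjusted p = 0.00343 and adjusted p = 0.756 with an estimated correlation. The aminoacyl-tRNA synthetases had 2 higher and 3 lower of 20 (4 and 4 adjusted over the list alone, 4 and 12 over all genes without 10 mM library 1), with camera adjusted p = 0.495, or, without 10 mM library 1, adjusted p = 0.0315 and adjusted p = 0.765 with an estimated correlation. The stress kinase list had 5 higher and 1 lower of 20 (6 and 2 adjusted over the list alone, 12 and 2 over all genes without 10 mM library 1) at that dose, with camera adjusted p = 0.280, or, without 10 mM library 1, adjusted p = 0.0259 and adjusted p = 0.481 with an estimated correlation. Between the doses ribosome biogenesis had 1 higher and 0 lower of 26 (1 and 0 adjusted over the list alone, 17 and 0 over all genes without 10 mM library 1), with camera adjusted p = 0.612, or, without 10 mM library 1, adjusted p = 1.60e-04 and adjusted p = 0.979 with an estimated correlation. Autophagy and lysosome genes had 3 higher and 0 lower of 25 (3 and 0 adjusted over the list alone, 14 and 1 over all genes without 10 mM library 1), with camera adjusted p = 0.221, or, without 10 mM library 1, adjusted p = 0.00766 and adjusted p = 0.973 with an estimated correlation, and the fibroblast markers 0 higher and 2 lower of 8 (0 and 3 adjusted over the list alone, 0 and 5 over all genes without 10 mM library 1), with camera adjusted p = 0.0257, adjusted p = 0.530 with an estimated correlation and adjusted p = 0.0622 without 10 mM library 1.

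In the KEGG pathways, 54 tested genes of ECM-receptor interaction held 5 higher and 28 lower at 16 mM, or 6 and 34 without 10 mM library 1 (camera adjusted p = 0.00278, and adjusted p = 0.993 with an estimated correlation). Ribosome biogenesis in eukaryotes held 21 higher and 3 lower of 71, or 44 and 4 without that library (adjusted p = 0.0126, and adjusted p = 0.993 with an estimated correlation). The pathway named herpes simplex virus 1 infection held 120 higher and 25 lower of 386, or 198 and 57 of 384 without that library (adjusted p = 0.00321, and adjusted p = 0.993 with an estimated correlation), and 245 of its tested members are zinc finger genes whose symbols begin with ZNF. Of these, 92 rose and 9 fell at 16 mM (median 0.32), 9 rose and 16 fell at 10 mM (median -0.05), and 80 rose and 0 fell between the doses (median 0.39; edgeR's quasi-likelihood test). Of 244 such genes tested without 10 mM library 1, 148 rose and 19 fell at 16 mM, 41 rose and 33 fell at 10 mM, and 150 rose and 5 fell between the doses. These genes share repeats of similar sequence, so reads can divide between paralogs, and their single values are uncertain.

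Genes with long genomic spans were lower at both doses. Without 10 mM library 1, the 240 tested genes spanning over 400 kb had a median log2 change of -1.48 at 16 mM (14 higher and 202 lower), -0.79 at 10 mM (5 and 185) and -0.54 between the doses (10 and 142). By the deposited coordinates, PARD3B (1076 kb), SDK1 (967.8 kb), NEGR1 (886.6 kb), INPP4B (869 kb), DPYD (843.3 kb) and ANO2 (416.9 kb) are of this length. The largest falls at 16 mM also held shorter genes, namely SORBS2 (370.8 kb), TNNT2 (26.78 kb) and MUC1 (23.51 kb). Transcript length and GC content are argued against as the whole cause, since the median at 16 mM was -1.36 after their trend, and so is a part of the libraries, since the highest median of any 16 mM library was -1.33. Low expression stays open, because the 49 such genes above the median expression had a median of -0.71. That expression was averaged over all libraries, treated ones included, so the genes that fell most were less likely to be kept. The value of -0.71 is drawn toward 0 by this choice, and the test cannot decide how much low expression adds. An order over all spans was broken, with medians at 10 mM of 0.03 under 20 kb and 0.06 from 20 to 50 kb, while above 20 kb the medians fell with each wider bin at both doses, a form written after the first had failed, and a loss that grows with span is a hypothesis that these values leave open.

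Other splits of the same libraries into groups of the same sizes, 100 per comparison with the real one included, tested whether chance could give counts as large. If the libraries are exchangeable, chance was excluded for the genes changed: the real split was the only 1 of 100 to reach its count in each comparison, with 2351 genes at 10 mM (highest other 1041), 4439 at 16 mM (2615) and 1777 between the doses (0). The same held for changes of at least 2-fold, with 629 (202), 1323 (780) and 315 (0), and for the overlap of both doses, 1803 (1). The counts of PI3K-AKT and MAPK-ERK members at 16 mM, 8 (5) and 7 (6), are part of the genes changed, so these splits say nothing of the pathways themselves. The sets of close libraries described next make exchangeability doubtful, and with those sets summed edgeR called 0 genes between the doses. Neither the splits nor the sums took into account that sets of different groups correspond in part. Chance was not excluded for the sets called by camera with a preset correlation. As many lists were called in 99, 88 and 95 of 100 splits at 10 mM, at 16 mM and between the doses (real 13, 8 and 9, highest other 22, 21 and 18), and as many KEGG pathways in 98, 65 and 98 (real 38, 5 and 25, highest other 121, 63 and 115).

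The libraries of each group fell into sets lying closer together than the rest. Over genes with at least 100 summed counts, 14 pairs within such sets differed by a chi-square per gene of 1.756 to 13.62 (r of 0.991 to 0.995), and 21 pairs between them by 23.11 to 66.27 (r of 0.977 to 0.989). The 5 pairs with 10 mM library 1 differed by 873 to 1100. No pair differed by as little as sampling noise, and each library was counted as the labels give it. This does not show that the libraries came from separate cultures, since repeat libraries of 1 culture can also differ by more than sampling noise, and the labels name no batch for these sets. The sets corresponded in part between groups, by the correlation across genes of deviations from the group means. 10 mM libraries 2 to 4 correlated at r of 0.333 to 0.434 with 16 mM libraries 1 to 3 and at -0.460 to -0.390 with 16 mM libraries 4 and 5. Control libraries 2 and 3 correlated at 0.242 to 0.302 with 10 mM libraries 2 to 4, whereas control library 1 stood at -0.134 to -0.0831. Control libraries 4 to 6 correlated at 0.155 to 0.261 with 16 mM libraries 4 and 5 and at 0.122 to 0.190 with 10 mM libraries 5 and 6. The latter correlated at 0.112 to 0.185 with 16 mM libraries 4 and 5. No reported fit took the sets as a block, since they come from the measured values, a limit the sums share. By library, LSS stood at 24.1, 16.5, 17.6, 46.3, 49.1 and 40.5 FPKM in control libraries 1 to 6 and at 33.3, 31.6, 32.5, 20.7 and 22.4 FPKM in 16 mM libraries 1 to 5, whereas POLR2A stood at 28.5, 30.5, 29.4, 34.7, 35.2 and 33.1 and at 118, 132, 124, 193 and 199 FPKM.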
